A study of Danio rerio with 6 samples.

How the data were processed

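Sorted RFP-positive blood progenitors of zebrafish embryos at 20 h post fertilization were profiled by RNA-seq, in 3 control libraries and 3 blf-/-;drl 4KO libraries. Per the labels' protocols, embryos were dissociated, RNA was extracted from the sorted cells, and libraries were made from 30000 cells each with a low-input kit. The deposited values are raw counts per Ensembl gene, 1 file for each sample with 32520 gene IDs. Per the submitters' processing notes, the authors used bcl2fastq, FastQC 0.11.9, HISAT2 2.2.1, SAMtools 1.10 and featureCounts 1.6.0 with the GRCz11 build. The strand setting, the annotation release and the treatment of reads that fit more than 1 gene are not given in the sources used here. Reads of near-identical copies, of overlapping genes and of antisense partners may therefore be divided in ways that cannot be checked.

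Groups and replicate numbers were taken from the sample titles. The labels do not say that the replicates came from separate clutches or sorts, so p-values measure only the spread between these samples, which may be technical. Counts of replicates were compared before averaging, and every pair of a group differed by far more than sampling noise (chi-square per degree of freedom of 35.9 to 46.2 among controls and 70.9 to 79.9 among blf-/-;drl 4KO libraries). Gene symbols came from a name table by Ensembl ID, which gives a symbol to 29201 IDs (89.8%). Of these, 12593 are in capitals in the style of human genes and are printed as listed, and 1719 symbols belong to 2 or more IDs. IDs without a symbol held 2.80% to 6.10% of the counts of a library. No coordinates are given, since the RefSeq gene table used for synonyms and for gene order is of another build (GRCz12tu).

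Total counts ranged from 12751618 to 18101975. edgeR 4.0.16 in R 4.3.3 was run on the deposited counts with filterByExpr, TMM factors, robust dispersion and the quasi-likelihood test, which left 14517 genes. The contrast is blf-/-;drl 4KO minus control, with 3 libraries in each group and no covariate. P-values were adjusted by Benjamini-Hochberg over these genes, with a threshold of 0.05. CPM are TMM-scaled, errors beside CPM and shares are SDs with n = 3, and the SE of a log2 fold change is its size divided by the square root of the F statistic. The biological coefficient of variation was 66.5%. Where a gene had 3 or fewer counts in a group, and for the drl genes, the ratio of summed scaled counts is given with a 95% exact binomial interval. Where it had 0, a lower bound against 3 counts over the group is given. Such intervals and bounds cover counting error only, since the libraries carry no molecular identifiers used here.

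Before the data were examined, 29 gene lists with at least 5 tested members were fixed for blood lineages, other cell types the sort could hold, and processes. List members were matched to the name table by symbol, by its capital form, by the capital form without the paralog suffix, by RefSeq synonym and by older name. That order was chosen after the name table was seen. Because several zebrafish paralogs share a capital symbol there, a list can hold more genes than were written. Lists were tested two-sided with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 29 lists. Of these, 20 were past the threshold, and 8 with a correlation estimated for each list: targeted genes, globins, heme and iron, erythroid program, cell cycle, myeloid, epidermis and periderm, and Hox genes. The targeted list had 5 members, all lower (camera adjusted p = 3.79e-43, adjusted p = 0.00573 with an estimated correlation). It holds blf and drl genes, which the labels give as mutant in the blf-/-;drl 4KO embryos. Its fall is thus a check of the labels and not a separate result, although it is counted among the 20 and the 8. Genes named in the text were fixed by a rule in 3 parts. The first part is blf and the drl family. The second is the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 5 CPM, no overlap between groups and a symbol that is not clone-based. The third is up to 4 members of smallest p from each blood or vessel list and up to 2 from each other list past the threshold, process lists included. Members behind a count of 5 or fewer are named after their values were seen.

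The same pipeline was tested on counts simulated with the means, library sizes and dispersions of these data, of which 13921 genes passed the filter. It recovered 5.15% of 97 genes changed 2-fold and 23.2% of 95 genes changed 4-fold, or 27.8% and 80.0% of those over 50 CPM, with 4 false calls among 31. Far fewer genes were changed there than the 3327 called in the data. Since the adjustment depends on that number, these recovery rates may not hold for the data. Alternatives were RLE factors, library totals, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 10 CPM in 3 libraries, removal of globin and mitochondrial genes, stricter thresholds, a replicate block, each library left out in turn, an estimated correlation and fry. Added after the data were seen were globins with the HBE1 genes, leaving out control replicate 1 together with blf-/-;drl 4KO replicate 3, and a test of symbol families. DESeq2 gave no adjusted p for 13140 genes, which stayed out of its counts. Figures were drawn with matplotlib.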

Results

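RNA-seq was carried out on blood progenitors of zebrafish (Danio rerio) embryos at 20 h post fertilization. The cells carried red fluorescent protein (RFP) expressed from a gene-trap allele of blf, and each library was made from 30000 RFP-positive cells that had been sorted by flow cytometry after Liberase digestion. blf and the draculin (drl) genes encode zinc finger proteins of blood-forming mesoderm. There were 3 control libraries and 3 libraries from blf-/-;drl 4KO embryos, mutant for blf and drl genes. The labels differ on the controls: the sample genotype field gives blf-/-, whereas the series design gives blf+/-. With blf-/- controls, the labelled genotypes of the groups would differ in the drl genes alone. Total counts were 13997561, 14202026 and 12751618 in control replicates 1, 2 and 3. The corresponding totals were 18101975, 15313473 and 14063972 in blf-/-;drl 4KO replicates 1, 2 and 3.

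The design has a single comparison, of progenitors mutant for blf and drl genes with control progenitors at the same stage. Red cell genes fell together in the blf-/-;drl 4KO cells. The globin genes took 18.9% ± 1.19 of all counts in the controls and 4.47% ± 0.862 in the blf-/-;drl 4KO libraries (SD, n = 3 each). Of 32 tested members of the erythroid program list, 25 fell and 0 rose. Myeloid genes moved the other way, with 42 of 56 tested members higher and 0 lower, and 26 of 42 cell cycle genes fell. Of epidermis and periderm genes, 15 of 23 were higher.

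The targeted genes were measured first, in every library. blf (ENSDARG00000043126) was at 2571, 2526 and 2835 CPM (read counts scaled for library size) in control replicates 1, 2 and 3, and at 118, 80.2 and 45.3 CPM in the blf-/-;drl 4KO replicates. Its log2 fold change was -5.02 (SE 0.31, adjusted p = 1.97e-06, edgeR), and 4453 reads were still assigned to it over the 3 blf-/-;drl 4KO libraries. Whether reads of the gene-trap fusion transcript count toward blf is not given in the sources used here, so its values in both groups may include or miss them. For the same reason, the fall of blf does not settle which genotype label of the controls is right. drl (ENSDARG00000078004) had 21322 reads over the controls and 7 over the blf-/-;drl 4KO libraries, a ratio of 4383 after scaling (95% exact binomial interval 2127 to 10903). drll.1 (ENSDARG00000035151) had 22955 reads against 9, a ratio of 3670 (1933 to 8027). drll.2 (ENSDARG00000035150) had 11332 reads against 2, a ratio of 8153 (2256 to 67330). drll.3 (ENSDARG00000095635) had 1255 reads against 11, a ratio of 164 (91.4 to 330). All 5 genes were past the threshold and without overlap between the groups. The drl genes are close copies of one another, and drl and drll.1 overlap in the gene table used for neighbours, so reads could have been split between them. The RFP used for the sort is read from the blf locus, whose transcript differed between the groups.

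**Figure D1:**
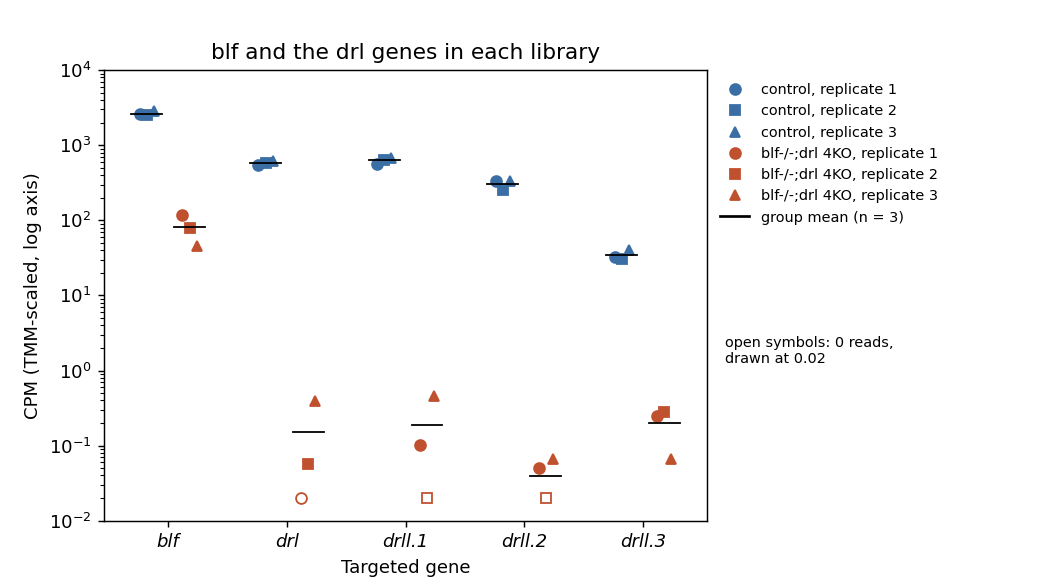
Each point is the CPM of a targeted gene in a library, on a log axis, with circles, squares and triangles for replicates 1, 2 and 3, blue for control and red for blf-/-;drl 4KO, and a black line at each group mean (n = 3). blf lies between 2526 and 2835 CPM in the controls and between 45.3 and 118 CPM in the blf-/-;drl 4KO libraries, and open symbols at the foot mark libraries with 0 reads.

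Among the globins, the oxygen carriers of red cells, 7 of 8 tested members fell and 0 rose (median log2 fold change -3.01, camera adjusted p = 2.13e-21, and adjusted p = 0.0493 with an estimated correlation). The alpha-type embryonic globin hbae1.1 went from 62738 ± 8973 to 7395 ± 1497 CPM, 8.48-fold lower (log2 fold change -3.08, SE 0.16, adjusted p = 4.7e-07). hbbe3 was 9.18-fold lower, hbae3 7.79-fold lower and hbae4 8.38-fold lower. The globin genes are near-identical copies in tandem, so their single values are uncertain where reads fit more than 1 of them. Adjusted over the list alone, 7 globins fell. With the genes that the name table lists as HBE1 added, 11 of 13 fell. In the heme and iron list, 20 of 26 members fell and 1, the iron exporter SLC40A1, rose from 3.59 to 24.2 CPM, with the same counts when adjusted over the list alone (median -2.54, camera adjusted p = 1.18e-34, and adjusted p = 0.0113 with an estimated correlation). alas2, the first enzyme of heme synthesis in red cells, fell from 2514 ± 157 to 298 ± 21.8 CPM (log2 fold change -3.08, SE 0.14, adjusted p = 2.71e-07). The heme enzyme genes UROD and CPOX were 7.95-fold and 8.45-fold lower.

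The erythroid program list, of red cell transcription factors, membrane skeleton and band 3, had 25 of 32 members lower and 27 when adjusted over the list alone (median -2.87, camera adjusted p = 6.74e-43, and adjusted p = 0.0109 with an estimated correlation). SPTB, which encodes the red cell beta spectrin, went from 1223 ± 61.0 to 91.9 ± 10.3 CPM, 13.3-fold lower (log2 fold change -3.73, SE 0.16, adjusted p = 2.71e-07). The zinc finger gene znfl2a was 11.5-fold lower, and SLC4A1 (ENSDARG00000012881, 1 of 2 genes with that symbol), which encodes the anion exchanger band 3, was 6.55-fold lower. The summed CPM of the erythroid program list was 22250 ± 1198 in the controls and 2851 ± 75.5 in the blf-/-;drl 4KO libraries, 7.80-fold lower. In the same blf-/-;drl 4KO libraries the summed CPM of the epidermis list was 8.38 times that of the controls.

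**Figure D2:**
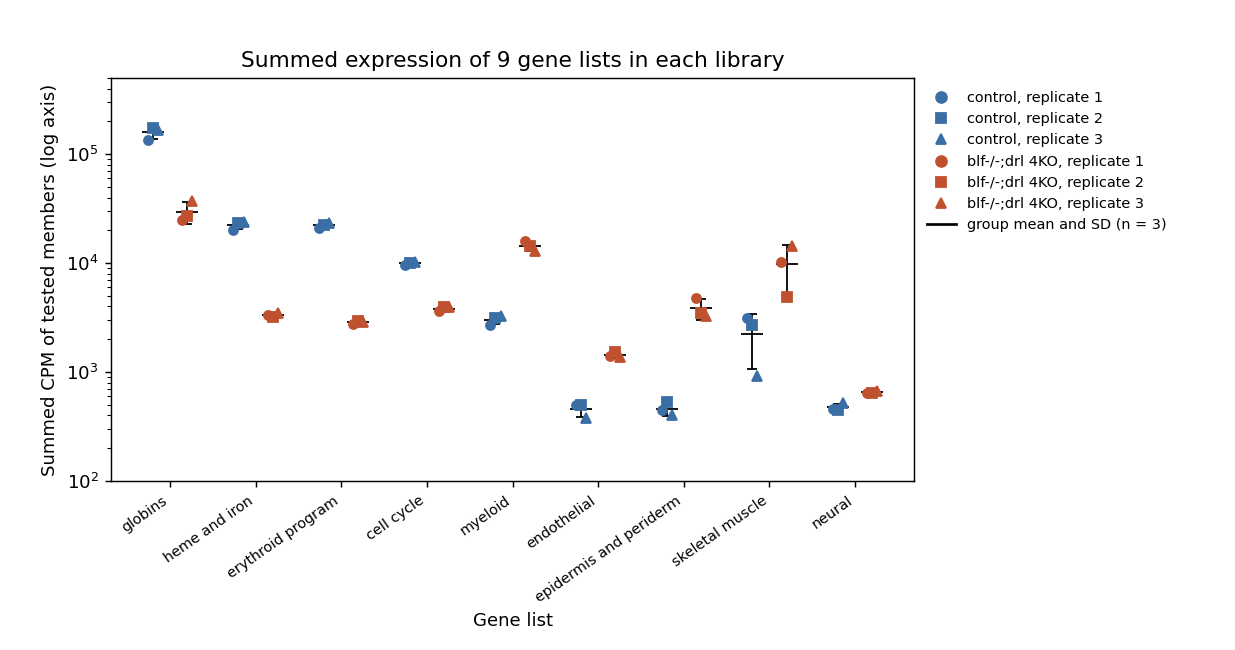
Each point is the summed CPM of the tested members of a gene list in a library, on a log axis, with blue for control, red for blf-/-;drl 4KO, and black bars for the group mean and SD (n = 3). The erythroid program sums lie at 22250 ± 1198 CPM in the controls and 2851 ± 75.5 CPM in the blf-/-;drl 4KO libraries, and the myeloid sums lie at 3030 ± 289 and 14362 ± 1408 CPM.

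Genes of the cell cycle fell in the blf-/-;drl 4KO cells, 26 of 42 lower and 1, CCND2 (ENSDARG00000051748), higher, and 32 lower and 1 higher when adjusted over the list alone (median -1.26, camera adjusted p = 1.61e-15, and adjusted p = 0.00983 with an estimated correlation). RRM2 (ENSDARG00000020711, 1 of 2 genes with that symbol), a subunit of ribonucleotide reductase, went from 128 ± 13.7 to 3.41 ± 0.501 CPM, 37.4-fold lower (log2 fold change -5.22, SE 0.32, adjusted p = 1.89e-06). The other gene listed as RRM2 (ENSDARG00000078069) had more counts in the controls and fell less, from 467 to 193 CPM (log2 fold change -1.27, adjusted p = 0.000503, edgeR). The cyclin gene CCND1 was 4.84-fold lower. Of 91 genes with ribosomal protein symbols, 74 fell and 2 rose, or 78 and 3 when adjusted over the list alone (median -0.79, camera adjusted p = 1.05e-15), a call that was lost at adjusted p = 0.268 with an estimated correlation. The members that rose were rps27l and RPS6KA3, a kinase gene whose symbol fits the pattern of the list. RPLP0 fell 2.33-fold and RPS10 2.18-fold. The median stayed below 0 under each scaling, at -0.47 with library totals. Among proteasome subunits 9 of 42 fell and 0 rose, or 7 and 0 when adjusted over the list alone (median -0.45, camera adjusted p = 0.00419), with adjusted p = 0.317 with an estimated correlation, 0.077 with library totals and 0.0834 with no filter. Both named subunits, PSMB5 (log2 fold change -0.75, SE 0.17) and PSMA4 (log2 fold change -0.69, SE 0.17), were past the threshold with TMM and not with library totals, DESeq2 or no filter. Without control replicate 2 they were at adjusted p = 0.0567 and 0.085, and PSMA4 was at 0.0849, 0.0662 and 0.0746 without control replicate 3 and blf-/-;drl 4KO replicates 1 and 2.

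Transcription factors of early blood moved in both directions, and the blood progenitor list as a whole did not pass (camera adjusted p = 0.502, 0.562 with an estimated correlation). Of its 15 tested members 3 fell, 4 rose and 8 did not pass, and 5 fell and 4 rose when adjusted over the list alone. Its median was 0.41 while its mean was -0.04 and the test pointed down. TAL1, a master regulator of blood and vessel fate, fell from 504 ± 12.5 to 108 ± 10.5 CPM (log2 fold change -2.22, SE 0.17, adjusted p = 5.88e-06). Its partner LMO2 fell from 1330 ± 107 to 253 ± 92.7 CPM (log2 fold change -2.40, SE 0.25, adjusted p = 7.64e-05). The third that fell was IKZF1 (log2 fold change -1.18), and those that rose included FLI1 (1.26) and CBFB (1.16), which were picked after their values were seen. etsrp, the ETS factor that starts the vascular program, rose from 23.1 ± 5.35 to 115 ± 11.7 CPM (log2 fold change 2.31, SE 0.29, adjusted p = 0.000249), and the chemokine receptor gene CXCR4 (ENSDARG00000041959) rose 2.49-fold. Of the 15 members 3 were also in another list, and all 3 rose. These were etsrp and FLI1, in the endothelial list, and CXCR4, in the myeloid and adhesion lists, so their rises are counted there too. The thrombocyte list had 3 members lower and 3 higher of 11 (3 and 4 when adjusted over the list alone) and did not pass (median 1.01, camera adjusted p = 0.556, 0.612 with an estimated correlation). Its platelet glycoprotein gene gp9 was 17.6-fold lower, at 64.1 ± 27.8 against 3.63 ± 0.905 CPM, and GP1BB and GFI1B were the other members that fell. The integrin-binding gene FERMT3 (ENSDARG00000079267) was 4.05-fold higher, and the 2 genes listed as THBS1, for thrombospondin, were 4.75-fold and 24.0-fold higher.

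Genes of macrophages and neutrophils rose in the blf-/-;drl 4KO cells. Of 56 tested myeloid members 42 rose, 0 fell and 14 did not pass, and 49 rose when adjusted over the list alone (median 2.18, camera adjusted p = 5.34e-32, and adjusted p = 0.0113 with an estimated correlation). The macrophage gene MFAP4 (ENSDARG00000089667, 1 of 8 genes with that symbol) went from 59.3 ± 8.65 to 1009 ± 162 CPM, 17.0-fold higher (log2 fold change 4.09, SE 0.20, adjusted p = 3.67e-07). The MFAP4 copies may share reads. Of the 56 members, 48 had a mean of at least 5 CPM in the controls and 1 was also in another list. The leukocyte plastin gene LCP1 was 5.23-fold higher (156 ± 14.9 against 817 ± 112 CPM), and the myeloid transcription factor CEBPB was 4.85-fold higher. The Fc receptor chain gene fcer1gl was 6.22-fold higher. The summed CPM of the list was 3030 ± 289 in the controls and 14362 ± 1408 in the blf-/-;drl 4KO libraries, a ratio of 4.74, while the ratio for the epidermis list was 8.38. The ratio for the neural list was 1.38, and 3.61 without DLD, whose capital symbol is that of a metabolic enzyme, and STMN1 (ENSDARG00000004169), both picked after their values were seen, which held 402 of the 474 CPM of that list in the controls.

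Vessel genes were also higher, with 14 of 37 endothelial members up and 0 down, or 14 and 1 when adjusted over the list alone (median 1.51, camera adjusted p = 5.81e-05). The endothelial call was lost with an estimated correlation (adjusted p = 0.147). Of these 37, 20 had a mean of at least 5 CPM in the controls and 6 were also in another list. ramp2, a coreceptor of the adrenomedullin pathway, rose from 13.4 ± 5.09 to 108 ± 21.5 CPM (log2 fold change 3.01, SE 0.36, adjusted p = 0.000182). The endothelial cadherin gene cdh5 rose 6.07-fold and the phosphatase gene DUSP5 3.13-fold. Of Notch pathway genes 9 of 24 rose and 0 fell (median 1.94, camera adjusted p = 0.000558, adjusted p = 0.0771 with an estimated correlation), among them the Notch targets NRARP (ENSDARG00000091419), 3.45-fold, and her15.2, 7.06-fold. Without control replicate 1 and blf-/-;drl 4KO replicate 3 these 2 genes were at adjusted p = 0.0509 and 0.0501. The 24 Notch members include DLD, whose capital symbol is that of a metabolic enzyme and which did not pass. BMP and TGF-beta genes rose in 9 of 28 cases and fell in 0 (median 1.72, camera adjusted p = 0.000897, adjusted p = 0.102 with an estimated correlation); the ligand gene tgfb1a was 9.88-fold and the BMP target ID3 3.99-fold higher. Of cell adhesion and migration genes 19 of 41 rose and 0 fell (median 1.72, camera adjusted p = 1.65e-05, adjusted p = 0.0596 with an estimated correlation). These included the epithelial cadherin gene cdh1, 6.24-fold, and the leukocyte integrin gene itgb2, 4.60-fold higher. Adjusted over the list alone, 14 Notch, 10 BMP and TGF-beta and 19 adhesion genes rose, and 1 BMP and TGF-beta gene fell. In the controls, 9 of 24 Notch, 8 of 28 BMP and TGF-beta and 22 of 41 adhesion members had a mean of at least 5 CPM. Members low in the controls could pass the expression filter through the blf-/-;drl 4KO libraries alone, which favours rises in these lists. Of the Notch members 5, and of the adhesion members 4, were also in another list.

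Among lists for tissues outside the blood and vessels, only the epidermis list was past the threshold also with an estimated correlation. The Hox list, set by a symbol pattern and not by a tissue, was past it as well. In the epidermis and periderm list 15 of 23 members rose and 0 fell (median 2.88, camera adjusted p = 3.63e-18, and adjusted p = 0.0292 with an estimated correlation). The tight junction gene cldni went from 0.467 ± 0.104 to 148 ± 17.0 CPM and the keratin gene krt4 from 14.9 ± 6.53 to 540 ± 176 CPM, 36.3-fold higher (adjusted p = 4.21e-06, edgeR). Hox genes, which pattern the body axis, rose in 18 of 40 cases and fell in 0 (median 2.77, camera adjusted p = 2.24e-09, and adjusted p = 0.0469 with an estimated correlation); HOXB8 was 12.7-fold and HOXD10 29.4-fold higher. Skeletal muscle genes rose in 13 of 27 cases and fell in 0 (median 1.99, camera adjusted p = 4.84e-07, adjusted p = 0.286 with an estimated correlation). The titin gene TTN (ENSDARG00000028213) was 3.96-fold higher, and the calcium store gene CASQ1 (ENSDARG00000018105) was 21.3-fold higher but at adjusted p = 0.0671 without control replicate 1 and blf-/-;drl 4KO replicate 3. Collagens rose in 13 of 48 cases and fell in 0 (median 1.88, camera adjusted p = 1.65e-05, adjusted p = 0.218 with an estimated correlation); COL1A2 was 9.76-fold and COL5A2 6.64-fold higher. Adjusted over the list alone, 16 epidermis, 22 Hox, 19 muscle and 13 collagen genes rose and 0 fell. In the controls, 10 of 23 epidermis, 8 of 40 Hox, 14 of 48 collagen and 24 of 27 muscle members had a mean of at least 5 CPM. Members low in the controls could pass the expression filter through the blf-/-;drl 4KO libraries alone, which favours rises in such lists.

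In the yolk, endoderm and hatching gland list 4 of 12 rose (camera adjusted p = 0.00493, adjusted p = 0.204 with an estimated correlation and 0.053 with no filter). These were apoeb, an apolipoprotein gene, 7.94-fold higher, CD63, 3.78-fold higher, and FOXA1 and foxa3, picked after their values were seen. In the notochord, tailbud and paraxial mesoderm list 1 of 13 rose, cdx4, from 0.156 ± 0.136 to 21.0 ± 8.18 CPM (median 2.30, camera adjusted p = 0.0143, adjusted p = 0.218 with an estimated correlation, and 0.105 without blf-/-;drl 4KO replicate 1). Its member dlc was at log2 fold change 2.30 (SE 0.82, adjusted p = 0.0672) and did not pass, whereas it did with library totals (adjusted p = 0.0374), DESeq2 (0.000173), limma-voom (0.0346) and the 10 CPM filter (0.0273). The cardiac and endocardial list had 3 of 7 members higher (median 1.87, camera adjusted p = 0.0185, adjusted p = 0.147 with an estimated correlation). These were actc1a, 3.66-fold higher, at adjusted p = 0.0878 without control replicate 1 and blf-/-;drl 4KO replicate 3, and both genes listed as MEF2C. The list's adjusted p was 0.111 with the 10 CPM filter and 0.225 with no filter. It was 0.118 without control replicate 2 and 0.0914, 0.0917 and 0.136 without blf-/-;drl 4KO replicates 1, 2 and 3. The neural list (7 of 28 higher, and GFAP lower, median 1.04, camera adjusted p = 0.0858, 0.268 with an estimated correlation) and the pronephros list (CDH17, PAX2 (ENSDARG00000028148), OSR1 and SLC12A3 of 13 higher, and SLC20A1, ENSDARG00000020114, lower, median 1.79, camera adjusted p = 0.219, 0.286 with an estimated correlation) did not pass. Adjusted over the list alone, 4 yolk, 1 notochord, 5 cardiac, 8 neural and 6 pronephros genes rose, and 1 neural and 1 pronephros gene fell. In the controls, 3 of 12 yolk, 4 of 13 notochord, 4 of 7 cardiac, 6 of 28 neural and 7 of 13 pronephros members had a mean of at least 5 CPM. The expression filter could therefore favour rises in these lists as well. The neural list was past the threshold with no filter (adjusted p = 0.0126) and without control replicate 1 (adjusted p = 0.0412), control replicate 2 (0.0258) or blf-/-;drl 4KO replicate 3 (0.0176), and without control replicate 1 and blf-/-;drl 4KO replicate 3 together (0.0184). With fry, which tests whether the members move on balance in a direction and does not compare them with other genes, the neural and pronephros lists were at adjusted p = 0.0132 and 0.00611. Libraries of a group differed in these tissues: the cartilage and notochord collagen COL2A1 (ENSDARG00000069093, picked after its values were seen) was at 104 CPM in control replicate 1 and at 1.24 and 2.18 CPM in control replicates 2 and 3. The summed muscle list was at 10284, 4854 and 14294 CPM in the blf-/-;drl 4KO replicates, and replicate 3 lay apart from replicates 1 and 2 on the second principal component (13.8% of the variance).

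**Figure D3:**
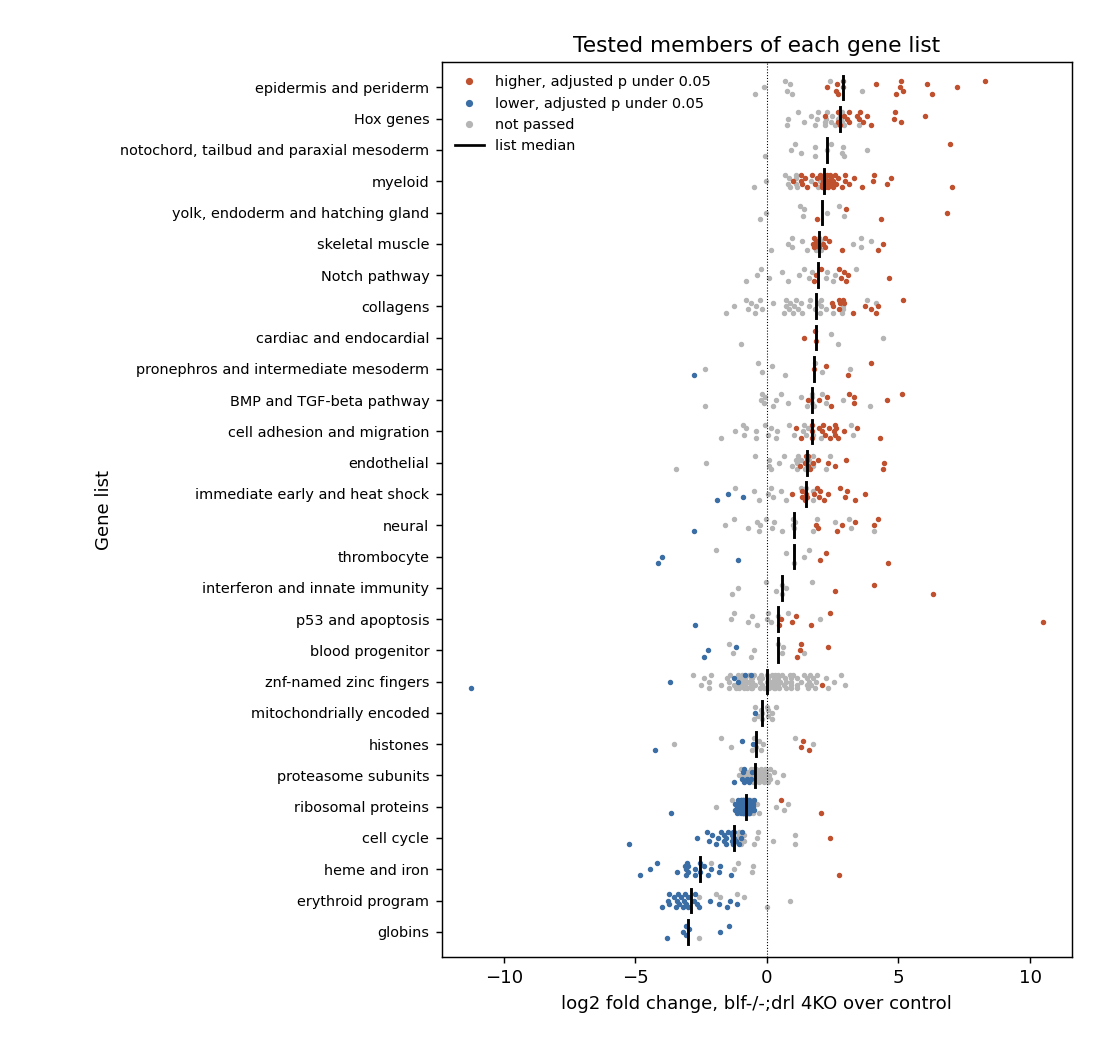
Each point is the log2 fold change, blf-/-;drl 4KO over control, of a tested member of a gene list, in red or blue where it was higher or lower past an adjusted p of 0.05 and grey where it was not, with a black line at the list median and the targeted genes left out. The medians shown run from -3.01 for the globins to 2.88 for epidermis and periderm, and the farthest point shown to the left is znf1156, with 0 reads in the blf-/-;drl 4KO libraries, where the plotted value depends on the prior count.

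Genes that respond to tissue dissociation moved in both directions, with more of them higher than lower. In the list of immediate early and heat shock genes 17 of 32 rose and 3 fell (median 1.47, camera adjusted p = 5.13e-05, adjusted p = 0.147 with an estimated correlation). The AP-1 gene FOSL2 was 6.83-fold higher, and the members that fell were the chaperone genes HSP90AA1, 3.68-fold lower, HSPA8 (ENSDARG00000068992) and hsp70.3. Another chaperone gene, hsp90aa1.1, picked after its values were seen, rose from 124 to 347 CPM. Adjusted over the list alone, 19 rose and 5 fell, and the summed CPM of the list was 0.859 times that of the controls. HSPA8 held 7171 of the 10135 CPM of that sum in the controls and 3832 of 8709 in the blf-/-;drl 4KO libraries. Its fall was larger than that of the sum, so the sum does not give the direction of the other members. The p53 and apoptosis list (7 of 19 higher and 1, RRM2B, lower, median 0.44, camera adjusted p = 0.121, 0.268 with an estimated correlation) and the interferon list (3 of 11 higher, among them isg15 and irf9, median 0.58, camera adjusted p = 0.182, 0.268 with an estimated correlation) did not pass. The p53 list was past the threshold with the 10 CPM filter (adjusted p = 0.0448) and with no filter (0.00513). With fry, adjusted p was 0.00459 for the p53 list, 0.00941 for the interferon list and 0.0339 for the znf list. Histones (3 higher, among them H1-10 and h2ax1, and H3C15, H2AZ2 and h3f3a lower of 17, median -0.42, camera adjusted p = 0.538, 0.653 with an estimated correlation) and zinc finger genes with znf symbols (1, znf346, higher and 6 lower of 104, camera adjusted p = 0.331, 0.268 with an estimated correlation) did not pass either. Adjusted over the list alone, the counts higher and lower were 7 and 1 for p53, 4 and 0 for interferon, 4 and 4 for histones, 1 and 4 for znf genes, and 0 and 0 for mitochondrially encoded genes. The znf median was 0.02, also with its member without reads at the bound, while its mean was -0.11 and the test pointed down. Of 13 mitochondrially encoded genes 1, MT-ATP6, fell (median -0.18 with TMM and 0.13 with library totals, camera adjusted p = 0.484, 0.733 with an estimated correlation), and these genes took 4.71% ± 0.573 of counts in the controls and 6.19% ± 0.131 in the blf-/-;drl 4KO libraries.

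The largest single rises included PHLDA3, a p53 target, with 2 reads over the controls and 4845 over the blf-/-;drl 4KO libraries, a ratio of 1684 (95% exact binomial interval 466 to 13906). The natriuretic peptide gene nppc had 1 read against 2262, a ratio of 1572 (282 to 62118), and the somatostatin gene SST had 2 against 2243, a ratio of 779 (216 to 6440). GPD1 (ENSDARG00000043701), a glycerol phosphate dehydrogenase gene, had 2 reads against 1866, a ratio of 648 (179 to 5358), and F2R (ENSDARG00000086236) had 1 against 554, a ratio of 385 (68.8 to 15234). aep1, lamp3, nuggc.2 and kng1 rose 541-fold, 383-fold, 295-fold and 285-fold. ECRG4 (ENSDARG00000056087), at a ratio of 579 (104 to 22893), and snorc, at a ratio of 419 (116 to 3461), rose unevenly. ECRG4 was at 2.92, 3.23 and 47.4 CPM and snorc at 24.3, 39.9 and 1.12 CPM in blf-/-;drl 4KO replicates 1, 2 and 3. Genes that fell to 0 reads included LSM10 (ENSDARG00000109563), with 1254 reads against 0, at least 601-fold lower, and znf1156, with 757 against 0, at least 363-fold lower, both against a floor of 3 counts over the group. The long noncoding RNA lnc.veal2 was 1791-fold lower (222 ± 28.3 against 0.124 ± 0.122 CPM, log2 fold change -10.81, SE 0.48, adjusted p = 2.71e-07). ANGPTL5, sytl1 and arhgef15b were 438-fold, 226-fold and 94.2-fold lower, UCK1 had 434 reads against 3, a ratio of 208 (70.8 to 1013), and PHB2 (ENSDARG00000045297, 1 of 2 genes with that symbol) was 87.2-fold lower.

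Of 14517 genes tested, 3327 were past an adjusted p of 0.05 in edgeR's quasi-likelihood test, 1887 of them higher and 1440 lower in the blf-/-;drl 4KO cells. A change of more than 2-fold was met by 1795 of the higher and 1136 of the lower genes. In 3303 of the 3327 genes the 3 values of one group did not overlap those of the other, and such separation was seen in 42.5% of all tested genes, where chance gives 10%. The higher genes made up 56.7% of the calls with TMM scaling and 71.5% with library totals alone (2402 higher and 959 lower). With DESeq2 they made up 64.9% (3158 higher and 1709 lower) and with no filter beyond 1 read 66.8% (2053 higher and 1021 lower). The median log2 fold change of all tested genes was 0.11, and scaling by library totals moved it up by 0.31. Leaving out control replicate 2 brought the lower genes down to 868, and leaving out both control replicate 1 and blf-/-;drl 4KO replicate 3, a choice made after the data were seen, brought the higher genes down to 1154.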

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

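Leaving out control replicate 1 with blf-/-;drl 4KO replicate 3 was chosen after the data were seen. The count of higher genes, 1887, was 3158 with DESeq2 and 969 at an adjusted p under 0.01, and lay between 1342 and 1551 with 1 library left out and at 1154 with that pair left out. The count of lower genes, 1440, was 959 with library totals and 769 at an adjusted p under 0.01, and lay between 868 and 1220 with 1 library left out; fewer samples and a stricter threshold account for part of this, and the cause was not tested for DESeq2 and library totals. The other alternatives stayed within 1.5 times of these counts. Of the 3327 genes, 2842 kept their call with library totals and 2956 with DESeq2. Replicate numbers did not pair the libraries (correlations of deviations between same-numbered libraries of 0.00, -0.04 and 0.00), and a replicate block gave 1651 higher and 1277 lower genes. The globin, heme, erythroid program and myeloid lists kept their call under every alternative run, with adjusted p up to 0.0493, 0.0113, 0.0109 and 0.0113. The endothelial list was lost with an estimated correlation (adjusted p = 0.147, and 6.04e-09 to 0.147 over its alternatives). That setting raised the camera adjusted p also for lists whose estimated correlation was below the preset 0.01. Cell cycle, at 0.000669, went from 1.61e-15 to 0.00983, and the cardiac list, at -0.0103, from 0.0185 to 0.147. Calls lost with this setting are therefore not explained by genes that vary together alone. Lists outside the threshold that changed direction were histones with the 10 CPM filter (adjusted p = 0.737), and mitochondrially encoded genes with library totals (0.79) and no filter (0.686); the cause was not tested. Over 78 named genes, 1140 of 1159 results under alternatives kept their direction and side of the threshold, 15 in 6 genes were no longer past it, 4 came past it, and 0 changed direction. In simulated counts 23.2% of 4-fold changes were recovered, and 80.0% of those over 50 CPM, and depth itself was not varied. Far fewer genes were changed in that simulation than were called in the data, so these rates may not hold here.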

Other observations

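The symbol family test and the tests of the share of globin and mitochondrial counts, of equal erythroid loss, of equal gains between cell types, of cells from the rest of the embryo and of other splits were chosen after the results were seen; the test of neighbours of the drl cluster was set before its result. Genes grouped by the letters that open their symbol showed groups that moved together, some of them made up of genes of the lists above. Of 165 such families with at least 10 tested members, 26 were past the threshold (camera, adjusted over the families), 12 higher and 14 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.339. The 26 are not all separate results. MFAP, KRT, RPL, RPS, MCM, COL, HOXB and HOXC hold genes of the myeloid, epidermis, ribosomal, cell cycle, collagen and Hox lists. The ARPC and IL families share ARPC1B, il6r and il1b with the myeloid list, and annexins share anxa1c with the epidermis list. Translation initiation factors (EIF) had 36 of 63 members lower and 1, eif4ebp1, higher (median log2 fold change -0.91, adjusted p = 6.79e-10, 0.474 with an estimated correlation). Nucleoporins (NUP) had 11 of 21 lower and 0 higher (adjusted p = 4.12e-06, 0.339 with an estimated correlation), RNA polymerase subunits (POLR) 11 of 31 lower and 0 higher (adjusted p = 0.000211, 0.398 with an estimated correlation), and proteins of the large mitochondrial ribosome subunit (MRPL) 14 of 47 lower and 2, MRPL23 and MRPL24, higher (adjusted p = 0.00153, 0.60 with an estimated correlation). The ARPC family, subunits of the complex that branches actin filaments, had 8 of 10 members higher and 1, ARPC5L, lower (median 1.65, adjusted p = 6.47e-05, 0.339 with an estimated correlation). Genes whose symbols open with IL, as those of interleukins do, had 8 of 23 higher and 0 lower (median 2.09, adjusted p = 0.00261, 0.339 with an estimated correlation), and annexins (ANXA) 7 of 14 higher and 1, ANXA11, lower (median 1.85, adjusted p = 0.0266, 0.398 with an estimated correlation).

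The real split of the 6 libraries gave 3327 genes in edgeR, and the highest count from the other splits was 0 (5135 against 342 at an unadjusted p under 0.05, and 4867 against 113 in DESeq2). Of 10 splits, 1 gave as many genes, and 10 splits are too few for a share under 0.05.

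The fall of red cell genes was set against 2 explanations. Abundant globin and mitochondrial transcripts did not take up more of the counts in the blf-/-;drl 4KO libraries. The share left to other genes was higher there (89.3% ± 0.744 against 76.4% ± 0.669, SD, n = 3, a log2 ratio of 0.226). That value follows from the globin and mitochondrial shares given above, and the globins are among the genes that fell. It is therefore not a separate test of the fall. A loss of red cell precursors with unchanged expression in those that remain would lower every such gene by about the same fold. The HBE1 genes, added after the data were seen, were counted among the globins here. I-squared, however, was 91.3% over the 55 erythroid, heme and globin genes that fell, and 94.9% over 11 globins, whose log2 fold changes ran from -4.90 to -1.43. It was 90.9% over all 70 tested members and 92.6% over the 26 with a control mean of at least 1000 CPM, although 17 of these 26 lay within 0.5 of their median log2 fold change. This argues against equal loss as the whole cause and leaves a like loss as part of it open, and reads shared between globin copies and expression of some members in other cells may add to the spread.

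The rise of markers of other cell types was set against a smaller erythroid share and against cells from the rest of the embryo. A smaller erythroid share alone would raise the other lists alike if none of their members were expressed in the red cells. The myeloid, endothelial, epidermis, muscle and neural lists differed (permutation p = 1e-04 over 171 genes, with 9 of 100000 permutations as large, 0.00088 over 108 genes with a control mean of at least 5 CPM, and 0.00026 without DLD and STMN1, over genes, which are not independent replicates). Members also expressed in red cells could give such a difference. Genes that vary together, as in the muscle list (estimated correlation 0.649), make the p too small. The difference therefore does not exclude a smaller erythroid share. For the myeloid part, the gain in summed neural CPM was at most 0.0203 of the gain in summed myeloid CPM in a blf-/-;drl 4KO library (0.0178 without DLD and STMN1), which decides nothing without levels from whole embryos. For the skin and muscle part, the medians of 7 of 7 lists from other tissues lay above 0 (10 of 23 epidermis and 24 of 27 muscle members were also at 5 CPM or more in the controls), with krt4 at 540 CPM, and in both parts embryo cells that passed the RFP gate cannot be told apart from a change in the sorted cells themselves, because sort and genotype go together and the RFP is read from blf. An effect of the genotype on the sorted cells stays open and was not tested.

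Targeted genes aside, 17 genes past the threshold with a mean of at least 5 CPM had 3 or fewer reads in a group, 13 in the controls and 4 in the blf-/-;drl 4KO libraries, the latter LSM10, znf1156, UCK1 and si:ch211-214b16.2. Sequence differences carried along with the drl cluster were predicted to place most of them near it. Of the 10 that could be placed in the gene order of the other build (GRCz12tu), 0% lay within 25 protein-coding genes of the cluster, where 40 of 50 neighbours (80%) were matched to an ID. Such differences need not account for most of the 17, since 13 were low in the controls, where many other genes were also lower. Of the 4 low in the blf-/-;drl 4KO libraries, znf1156, UCK1 and si:ch211-214b16.2 were placed. The check thus covers only the placed genes and that window, and decides nothing about a longer carried stretch. The other 7 of the 17, LSM10 among them, were not placed and stay open. The same check around blf was void, since 50% of its neighbours were matched, and strain differences elsewhere in the genome were not tested.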
